A study of Solanum lycopersicum x Solanum habrochaites with 4 samples.

How the data were processed

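RNA of isolated leaf trichomes was measured on 4 2-colour arrays, each with a high and a low methylketone bulk of 5 plants. Plants were grown in pots in a net house in summer, and total RNA was taken with a plant RNA column kit, per the labels' protocols. Amplified RNA was labelled with Cy3 or Cy5. Per the file headers, the authors' intensity values are the mean brightness of each spot and the median brightness of its local background, taken from scans with Agilent Feature Extraction 9.5.1.1. The same deposited files hold processed signals, for which Feature Extraction subtracted the background and normalised the dyes. They also hold a log10 ratio of red over green, per the file headers, which the deposited value table repeats. In each array 100% of the table's values equalled that log10 ratio after rounding to 2 decimals, matched through the number in the probe name, and each column had a median of 0. Between 15.2% and 19.1% of its values were listed at 0, and its sign was not turned for the dye exchange. The series' description names GeneSpring GX and Biointerpreter as the analysis software, with no further settings.

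From the intensities, the background was corrected with normexp (offset 50) and the log ratio was normalised by loess within each array, in limma 3.58.1 under R 4.3.3. The 1417 control spots had weight 0 in loess and were left out of the tests. Ratios were turned so that a positive value means more in the high methylketone bulk, which was in Cy3 on arrays 1 and 3 and in Cy5 on arrays 2 and 4. A probe was tested if it was well above background in the high bulk on all 4 arrays or in the low bulk on all 4. Of 28272 such probes, 31 with an outlier flag on an array were left out. Levels per channel were taken after loess and scaling of mean brightness between arrays. The 2 arrays of a pair, which the labels call a biological replicate and its dye exchange, were averaged and limma tested the 2 averages against 0, with Benjamini-Hochberg adjustment and 1 residual degree of freedom (prior 2.27). As a check of the pairing, deviations from the mean of the same orientation correlated at 0.87 between the arrays of a pair, which is 1 value for both pairs, since with 2 arrays per orientation the deviations of one pair are the negatives of the other's. The labels do not say whether the bulks of the 2 pairs came from different plants, so the p-values measure the spread between these pairs.

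The second result follows the submitters' rule of a mean log2 ratio of at least 1 in size, reproducible on all 4 arrays. Reproducible was read here as the same sign on all 4 arrays. All 43803 probes had the description Unknown and no table of gene names was used, so 0 of the 20 gene lists fixed beforehand (with markers of other leaf cells) could be matched. The tests of these lists, the rule for named genes and the check of direction on methylketone synthase probes were not run. In place of that rule, 2 probes per direction were named after their values were seen.

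Families of probes were formed by joining probes that share a stretch of 20 bases, leaving out stretches made mostly of 1 base or of fewer than 3 kinds of base, and 28241 tested probes gave 24006 families. Odds ratios were computed with statsmodels 0.14.6 and figures with matplotlib 3.10.9, in Python 3.11.15. The fits were tested on simulated data with a set of probes changed by known amounts before use. Alternatives fixed before the data were examined covered the background correction, the normalization, the filter, single arrays and pairs left out, the treatment of dye exchanges, the test and the deposited value table. Removal of the GC trend and the count over families were chosen after seeing the data. All 4 arrays lay on 1 slide, so slide could not be tested as a batch.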

Results

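Transcript levels were compared between leaf trichomes of tomato plants that accumulated much methylketone and plants that accumulated little. Methylketones are volatile ketones made from fatty acids in the glandular trichomes of some wild tomatoes, and trichomes are the hairs of the leaf surface. The plants were F2 offspring of the cultivated tomato M82 and the wild species Solanum habrochaites f. glabratum, and 5 plants made up each bulk. RNA of a high methylketone bulk and a low methylketone bulk was hybridised together, in 2 colours, on a custom tomato array. There were 4 arrays, which held 2 biological pairs of bulks, each measured once and once more with the dyes exchanged. The 2 arrays of a pair were averaged, so that n = 2 throughout, and this number limits the precision of every value.

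Each array carried 43803 probes of 60 bases, and 28241 of them were bright enough to be tested. The median green signal of the 4 arrays lay between 90.2 and 107, against a local background of 41 to 43, and the median red signal lay between 122 and 337, against a background of 52.5 to 57. The probes carried no gene description, so genes and pathways are not named here. The probe names fell into 3 kinds by their first letters. There were 6276 names that began with LH, 21526 that began with TC and 16001 of another form, and the files do not say what the letters mean. Of these, 87.5%, 72.6% and 44.5% were tested.

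The comparison asked which transcripts of the trichomes differed between the high and the low methylketone bulks. The direction of every ratio rests on the dye label of each channel. The series' own description assigns the dyes to control and test samples without naming the bulks, and on array 4 the second channel was read as Cy5 because both channels were labelled Cy3. In the high methylketone bulk, 443 probes were at least 2-fold higher with the same sign on all 4 arrays, and 444 probes were at least 2-fold lower. This follows the rule in the submitters' description, with reproducible on all 4 arrays read as the same sign. It was applied to ratios from normexp and loess. Where each array had to pass the 2-fold threshold, 314 probes passed (204 higher, 110 lower). On Feature Extraction's processed signals the same-sign rule was passed by 1835 probes (894 higher, 941 lower), and on the deposited value table by 1829 (894 higher, 935 lower). With the direction taken from the channel labels, the higher probes reached larger differences than the lower ones, and with all signs turned the lower probes would. At a log2 ratio of at least 2 in size there were 88 higher and 32 lower probes, at 3 there were 51 and 3, and at 4 there were 17 and 0. These are counts of probes, not of transcripts, and the 17 include 11 probes that fell into 5 groups of related sequence. Over families of probes that share 20 bases, the 2-fold rule was passed by 312 higher and 297 lower families. With median centring in place of loess, which moved the median log2 ratio of the tested probes from -0.032 to -0.23, the rule was passed by 219 higher and 881 lower probes, and the balance of the directions also differed between the pairs. Without pair 1 there were 811 higher and 655 lower probes, and without pair 2 there were 481 and 1058.

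With the main processing, no probe passed the test of the difference against the spread between the pairs. The limma fit on the 2 averaged pairs gave 0 probes at an adjusted p under 0.05, and the smallest adjusted p was 0.145. At an unadjusted p under 0.05 there were 3705 probes, 1932 higher and 1773 lower, where 1412 were expected by chance. That count depended on the processing: it was 6650 with median centring and 1954 with limma's trend and robust settings. The main fit on Feature Extraction's processed signals called 45 probes, 40 higher and 5 lower, and over families of probes that share 20 bases, a unit chosen after seeing the data, it called 10 families. Without array 1 it called 13 probes and without array 3 it called 4, but the dye effect does not cancel in a pair that lost an array. Treating the 4 arrays as separate replicates, which counts dye exchanges as biological replicates, limma called 1675 probes, and with the pair as a random block it called 1457. The correlation within pairs that the block fit used was only 0.08, so it too treated the 4 arrays almost as separate replicates. On simulated data, the fit on the 2 pairs found 0 of 68 probes changed by 2 on the log2 scale and 43 of 66 probes changed by 4. The simulation drew the spread between pairs without regard to the size of the change. It left 28041 of 28241 probes unchanged. The number found after adjustment depends on that share, which is not known for the arrays. On the arrays, the median SD between pairs was 0.24 for the higher and 0.5 for the lower probes past the fold rule. It was 0.17 over all tested probes. The 17 measured probes with a log2 ratio of at least 4 did not pass, so the simulated shares need not hold for strongly changed probes. In the same simulation the fit on 4 separate arrays called 501 of 28041 unchanged probes and the fold rule took up 352, so some of the 1675 and of the 887 probes are expected without any difference.

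A set of 11 probes stood above the other tested probes, each over 64-fold higher in the high methylketone bulk. Their mean log2 ratios ran from 6.97 to 7.50, single arrays gave 6.09 to 8.43, and the next probe had 4.95. In this set 10 probes had LH names and 1 had a TC name. They had 9 different sequences, which fell into 5 groups that shared no stretch of 20 bases. Probes for different parts of 1 transcript need not share such a stretch, so the number of transcripts in the set is not known. Their adjusted p lay between 0.145 and 0.19, so they did not pass the test with the main processing either. In the high bulk, 3 of the 11 probes were saturated on every array and 5 more on some of the arrays, so the mean ratios of these 8 are lower bounds and the order of the probes within the set is not known.

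**Figure D1:**
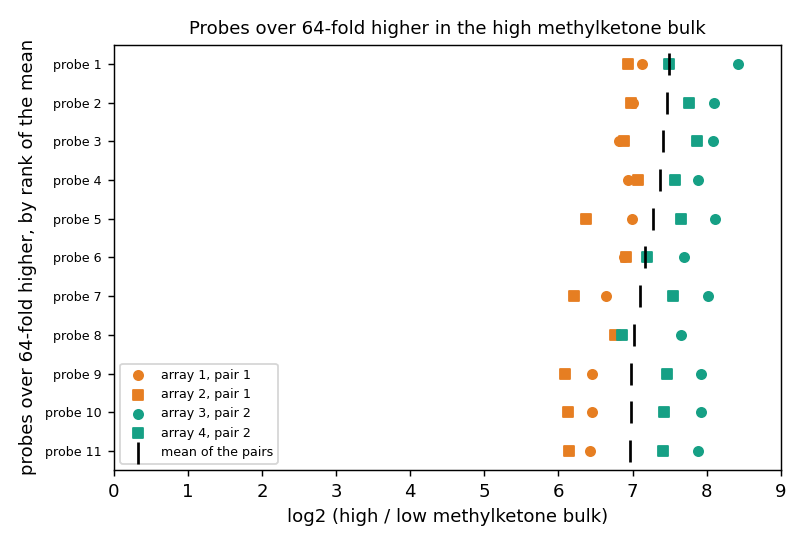
Log2 ratio of the high over the low methylketone bulk on the 4 arrays (symbols; orange for pair 1, green for pair 2) and its mean (bar) for each of the 11 probes over 64-fold higher, ranked by the mean. Single arrays lay between 6.09 and 8.43.

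The probes named here were chosen after their values were seen, as the probe with the highest measured ratio in the 2 highest groups of related probes and the lowest of the 2 lowest. Probe GT_TO_39777 (LH__Ea08I01.f), with the sequence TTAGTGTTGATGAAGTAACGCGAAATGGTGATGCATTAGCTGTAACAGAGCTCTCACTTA, had a log2 ratio of 7.50 ± 0.66 as measured (SD, n = 2; adjusted p = 0.145). Its normalised log2 level was 15.3 ± 0.05 in the high bulk and 7.81 ± 0.71 in the low bulk, and it was saturated in the high bulk on 1 array, which makes its level there and its ratio lower bounds. Probe GT_TO_41366 (LH__Ea08G22.r), with the sequence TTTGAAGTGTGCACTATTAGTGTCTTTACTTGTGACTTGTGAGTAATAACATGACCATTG, had a log2 ratio of 7.46 ± 0.66 (SD, n = 2; adjusted p = 0.145). On Feature Extraction's processed signals the limma fit gave both probes an adjusted p of 0.0351, with log2 ratios of 8.23 and 8.31. The deposited value table gave the same ratios with an adjusted p of 0.167, and with 1 array left out the adjusted p of these probes lay between 0.0387 and 0.0801.

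Among the lower probes, GT_TO_31785 (AW624755) had a log2 ratio of -3.95 ± 0.67 (SD, n = 2; adjusted p = 0.19). Its sequence was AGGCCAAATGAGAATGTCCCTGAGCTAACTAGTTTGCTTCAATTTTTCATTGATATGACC, and its normalised log2 level was 9.61 ± 0.03 in the high bulk and 13.57 ± 0.64 in the low bulk. Probe GT_TO_23764 (BI928250), with the sequence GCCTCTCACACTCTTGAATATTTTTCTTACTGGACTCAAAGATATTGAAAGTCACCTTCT, had a log2 ratio of -3.08 ± 0.60 (SD, n = 2; adjusted p = 0.19). The sign of these 4 probes was the same on all 4 arrays, as their choice among the probes past the fold rule required.

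The LH-named probes made up a larger part of the probes past the fold rule than of the tested probes. Of the 5494 LH-named probes tested, 329 (5.99%) passed the rule, against 448 of 15623 TC-named probes (2.87%) and 110 of 7124 other probes (1.54%). The LH-named probes were also brighter, with a median log2 intensity of 11.26 against 8.83 and 7.8. Within 10 brightness classes of equal size, the odds of passing were 1.62 times those of the other probes (95% interval 1.39 to 1.89, which treats probes as independent). Probes of 1 transcript are not independent, and the interval is too narrow for that reason.

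**Figure D2:**
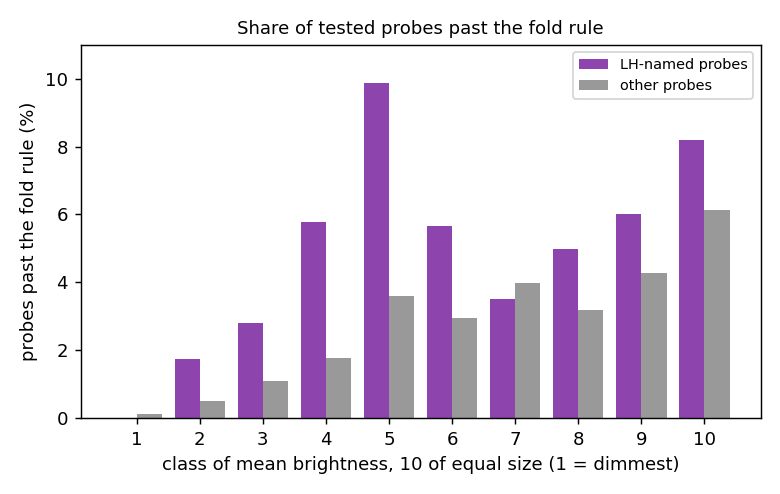
Percentage of tested probes past the fold rule in each of 10 classes of mean brightness (1 is the dimmest), for LH-named probes (purple bars) and all other probes (grey bars). In the brightest class the percentages were 8.19 and 6.12, and in classes 1 and 7 the LH-named probes had the lower percentage.

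Probes of identical sequence gave like values, and both ends of a clone less so. Of 935 sequences that were printed as 2 or more tested probes, the log2 ratio of the first 2 probes correlated at 0.996 across sequences, and their difference had an SD of 0.049. Where 1 or both of them passed the fold rule (57 sequences), both did in 55. Names that differed only in a final f or r were read as both ends of 1 clone. Of 1151 clones with both ends tested, the ends' log2 ratios correlated at 0.76 across clones. At least 1 end passed the rule in 114 clones, both ends passed in 51, and all 51 had the same direction at both ends. The ends differed by over 1 on the log2 scale in 44 clones.

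The pairs differed from each other as well. The log2 ratios of the 2 arrays of a pair correlated at 0.75 in pair 1 and 0.62 in pair 2 across probes, which are not independent replicates, while the means of the 2 pairs correlated at 0.36. The sign was the same on all 4 arrays for 8700 probes (30.8%). From the shares of probes with 1 sign on both arrays of each pair, 20.5% would be so if the pairs were unrelated.

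**Figure D3:**
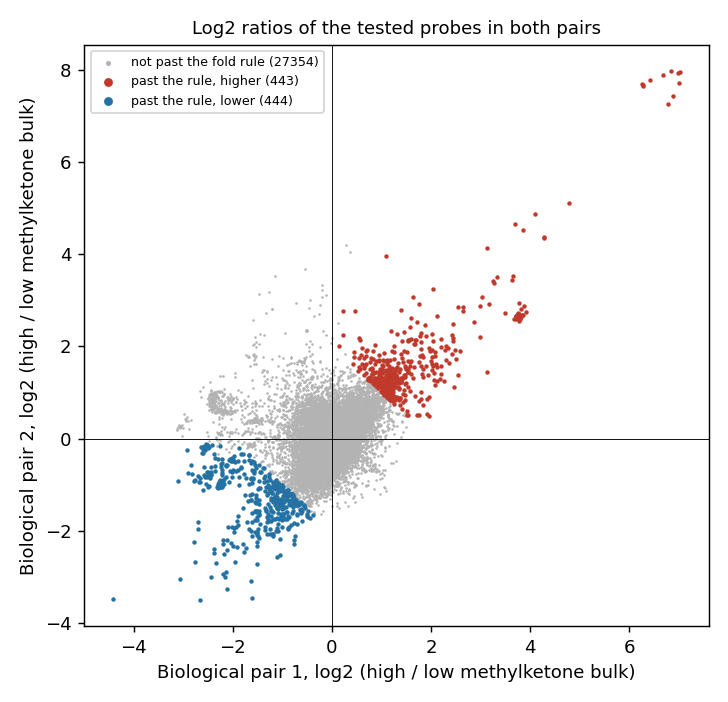
Log2 ratio of the high over the low methylketone bulk in biological pair 1 (x axis) and pair 2 (y axis) for the 28241 tested probes, with the 443 higher (red) and 444 lower (blue) probes past the fold rule. The pair means correlated at 0.36 across probes.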

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

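The tests of the set over 64-fold higher were chosen after the values they measure were seen. The other tests, with the GC removal and the families they use, were chosen after the data had been looked at but before their own results were seen, unless said otherwise. Of 16 measures checked for 1 array far from the other 3, 2 stood out, where chance flags about 1 in 20. The percentage of saturated green spots was 0.0731 on array 4 and at most 0.0137 on the others (gap over range 0.867). Red spots were saturated more often, from 0.979% on array 4 to 2.34% on array 3, without an outlying array (gap over range 0.383). The median log2 ratio of the tested probes was -0.013 on array 2 and between -0.036 and -0.033 on the others (gap over range 0.87).

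LH-named probes passed the fold rule more often than other probes. Brightness as the whole reason is argued against by the odds ratio of 1.62 within brightness classes, and repeated probes for 1 transcript by the odds ratio of 1.87 (95% interval 1.54 to 2.27) over families. With families compared within brightness classes, a value added afterwards, the odds ratio was 1.31 (1.07 to 1.61), so brightness and repeats together take up much of the excess. When the rule was applied to pair 1 against pair 2, 6.59% of the LH-named and 0.589% of the other probes passed, without correction for brightness or repeats, and 217 of these 496 probes belonged to 1 family. The design names no group that separates probe names, so no biological explanation was tested.

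Arrays of the same dye orientation correlated better across pairs (mean r 0.43) than arrays of opposite orientation (0.19). Removing each array's trend on GC content left 88.5% of this excess, which argues against GC content as its main source. The dye contrast correlated at 0.95 between probes of identical sequence at different spots, more than noise of single spots would give. The log2 ratio and the difference between pairs correlated at 0.996 and 0.99 between the same probes. Differences between bulks and between pairs cancel in the dye contrast, so these values do not bear on it. In a fit with bulk, dye and pair terms, the dye term had an SD of 0.22 across probes, against 0.08 for the remainder. The dye contrast thus followed the probe sequence, as a dye bias of each sequence would. Anything else that differed between the orientations by sequence would do the same, so this bias stays open as the source. A dye bias cancels in the mean of a pair, which holds both orientations.

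The 11 probes over 64-fold higher form 5 groups without a shared stretch of 20 bases, which argues against 1 faulty sequence. Saturation in the high bulk lowers a ratio, so the count of 3 probes saturated on no array decides nothing, and 0 probes of the set were saturated in the low bulk, where saturation would raise it. Hybridisation of the sequence of only 1 parent could produce part of the ratio and stays open. The TC-named probe differed from the median of the LH-named ones by -0.24 on the log2 scale, and this decides nothing: the files do not give the species of either kind of name, and the TC-named probe and 7 of the 10 LH-named probes were saturated in the high bulk on at least 1 array. A true difference in transcript level between the bulks is the other open explanation.

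The 887 probes past the fold rule can be set against other sign patterns of the 4 arrays. Of 8 patterns, 1 gave as many (the real one), the highest of the others gave 496, and 8 patterns are too few for a share under 0.05. That highest pattern sets pair 1 against pair 2 and is the only other one that keeps the arrays of each pair together. The rest turn arrays of a pair against each other, although these correlated at 0.75 and 0.62. Their counts of 0 to 49 were therefore low by construction. With 2 pairs, the patterns cannot say whether the 887 probes exceed chance.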

How the results depend on the processing

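The limma count of 0 probes remained 0 without background subtraction, with median centring, Aquantile scaling (which moves no ratio), no filter, the stricter filter, the deposited value table, trend and robust settings, 1 probe per name and, chosen after seeing the data, the GC trend removed. Feature Extraction's processed signals gave 45 probes, and families of probes (chosen after seeing the data) gave 10. The 4 arrays as separate replicates gave 1675, with a dye term 1683, and the biological pair as a replicate block 1457, where the dye exchanges add degrees of freedom. Leaving out 1 array gave 0 to 13 probes: 13 without array 1, 4 without array 3 and 0 without array 2 or 4. The dye effect does not cancel in the pair that lost an array. The fold rule's 887 probes became 1835 with processed signals and 1829 with the deposited value table, 314 when each array had to pass and 302 at a mean of 1.5. Counted over families of probes (chosen after seeing the data), 609 families passed the rule. Leaving out arrays gave 894 to 1539, the highest being 1466 without pair 1 (811 higher, 655 lower) and 1539 without pair 2 (481 higher, 1058 lower), which leave 2 arrays to share a sign. Of the 887 probes, 872 also passed with processed signals and 599 with median centring, where 1100 passed in all. Where no construction is named, the cause was not tested. The 4 named probes kept their direction in all 19 settings each. This is weak evidence, since they were chosen for extreme ratios on these arrays and several settings move no ratio. Their log2 ratios lay between 7.03 and 8.23 for GT_TO_39777, 7 and 8.31 for GT_TO_41366, -4.42 and -3.48 for GT_TO_31785 and -3.50 and -2.65 for GT_TO_23764. The limma adjusted p of the 4 probes ranged over the settings from 0.000249 to 0.552. The lowest came from a fit on 4 arrays, where dye exchanges add degrees of freedom. The gene list tests, the slide block and the turning of all signs were not run. Dim probes limit the ratios: 2 of the 443 higher and 4 of the 444 lower probes were not well above background in the dimmer bulk on any array. In both bulks on all arrays, 854 of the 887 probes were well above background (426 higher, 428 lower).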

Other observations

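By the same rule, 496 probes went opposite ways in the 2 pairs, and 492 of them were lower in the high methylketone bulk in pair 1 and higher in pair 2. Their median log2 ratio was -2.17 in pair 1 and 0.81 in pair 2. They belonged to 151 families, and 217 of the probes to 1 family alone, so the count holds far fewer transcripts than probes. LH names were carried by 362 of them, which is 6.59% of the tested LH-named probes against 0.589% of the others. The difference between the pairs correlated at 0.99 between probes of identical sequence at different spots. With the GC trend removed, 473 probes went opposite ways.

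Of 183 pairs of an LH-named and another probe that differed at 1 to 6 of 60 bases, the log2 ratio of the LH-named probe minus the other had a median of 0.01 and an SD of 0.15, and 1 pair differed by over 1.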
